A study of Mus musculus with 6 samples.

How the data were processed

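ATAC-seq was done on 6 samples of E14 mouse embryonic stem cells, 2 in each of 3 groups: 2iL medium, and 48 h and 96 h after 2iL was replaced by N2B27 medium without it. Per the labels' protocols, nuclei of 100000 live cells per sample were used, libraries were amplified for 10 PCR cycles, and fragments of 200 to 700 bp were selected on a gel. Nothing in the labels says whether samples A and B came from separate cultures. The submitters' processing notes name bcl2fastq 2.20.0.422, BWA, SAMtools and Picard and the genome build mm10, without their roles. The peak caller, its settings, any shift of reads for the transposase and the removal of duplicates or mitochondrial reads are not given in the sources used here. Each of these steps could change which weak peaks are listed.

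The files analysed are 3 deposited peak lists, 1 per group. The sample descriptions in the labels give samples A and B of a group the same list, so replicates had been pooled or combined by the authors, and 0 columns of values per sample were left unused. A line of a list holds an interval, a score, and for a summit within it a fold enrichment and a −log10 p. The deposited q values were not used here. The deposited fold is a linear ratio, the deposited p values are on the −log10 scale, and the deposited score is a whole number that is the same for all summits of an interval. Fold, p and score are the authors' values and were used only to describe, rank or filter regions within their own list. The lists held 187330, 185562 and 166089 summits for 2iL, 48 h and 96 h, in 91228, 88810 and 78055 intervals, all on chromosomes 1 to 19, X and Y. An interval took the values of its summit with the highest −log10 p.

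Depth is not given by a peak list, and was estimated from its values. The fold and p of a summit follow (k + 1) / (background + 1) and a Poisson tail for a pileup of k tags, and solving both gave a whole k, within a tolerance of 0.02, for 100% of the summits with a −log10 p under 290. These were 87.7%, 85.4% and 83.1% of the summits of the 3 lists. The most frequent background was 14.2, 15.2 and 13.99 tags per position, so the pooled 2iL libraries were 1.015 times as deep as those at 96 h and the 48 h libraries 1.07 times as deep as those in 2iL, if reads were extended equally. Tested on simulated data, k was recovered in 100% of 4986 summits. The simulated values were made with the same 2 formulas, so this checked the solution only. It did not check whether the background measures depth.

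The intervals of the 3 lists were merged into 131410 regions where they overlapped by at least 1 bp, and a region belonged to each list with an interval in it. A list held 2 samples but gave 1 value, so no test between conditions was possible and no p-value is given. Shares have exact (Clopper-Pearson) binomial 95% intervals, which cover counting error only and treat neighbouring regions as independent. Chance overlap came from 100 circular shifts of 1 list within each chromosome. Removing 20%, 40% or 60% of the 91228 intervals of the 2iL list at random, and moving the rest by up to 60 bp, gave lost shares of 20.02%, 40.02% and 60.01% when tested on these simulated data. The narrowest interval was 150 bp, so each moved interval still overlapped its original. This checked the counting only, and not the effect of changed widths, split intervals or limits that differ between lists.

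Gene positions came from an NCBI RefSeq gene table of GRCm38.p6, the same assembly as mm10. Summits lay within 200 bp of 29.1%, 30.5% and 29.8% of gene ends in the 3 lists, against 4.83%, 4.99% and 4.32% when gene positions were moved by 10 kb. This table has no strand or exons, so the planned distance to a transcription start was replaced by the distance to the nearer end of a protein-coding gene, and exons, introns and UTRs were not told apart. Each region went to the protein-coding gene with the nearest end within 100 kb of its summit. This placed 113835 regions, 86.6%, at 18242 of 21887 genes. A region assigned in this way need not act on that gene.

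Of 263 entries in 16 gene lists fixed before the data were examined, 262 matched a protein-coding gene (99.6%). The lists were naive, general, and formative and primed pluripotency, neural ectoderm, mesoderm and primitive streak, definitive endoderm, Hox, germline, 2-cell-like, WNT/beta-catenin, LIF/STAT3 and FGF/ERK targets, housekeeping genes, and markers of extraembryonic endoderm, trophoblast and fibroblasts. The lost or gained share of all regions at a list's genes was placed among 10000 random gene lists of the same size, matched on regions per gene, and percentiles under 2.5 or above 97.5 were taken as outside the random range. Genes are not replicates, so these percentiles describe the lists and test nothing between conditions. Random lists drew genes from the whole genome, so the random range may be too narrow for genes that lie side by side, as in Hox clusters. Over 16 lists, 3 comparisons and both directions, 96 shares were computed and 30 were outside the range, against 4.8 expected by chance if shares were independent. In simulations for 2iL against 96 h over 17398 genes, 2 of 100 lists of 20 genes with no effect and 82 of 100 with 15 percentage points more loss passed the upper limit. Apart from the added effect, every simulated gene had the same chance of loss and regions were independent. These rates need not hold for the real lists, where genes differ.

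Named genes followed a rule fixed before the data were examined: 31 marker genes, in each comparison the 5 genes with the highest net number of strong regions lost and the 5 with the highest gained (strong being the upper part of a list by fold, above its median), up to 3 members of each list with the most changed regions, and the 3 strongest lost and gained regions of each comparison. Some items that the rule names are not reported here. Alternatives covered the overlap required, stricter lists, lists of equal length, autosomes only, the definition of strong regions, the gene-end window and the assignment of regions to genes. Motif, GC, CpG and repeat content need a genome sequence and were not analysed here. Calculations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.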

Results

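Open chromatin was mapped by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in E14 mouse embryonic stem cells. The cells were kept in 2iL, a medium with the GSK3 inhibitor CHIR99021, the MEK inhibitor PD0325901 and the cytokine LIF, or were collected 48 h or 96 h after 2iL was withdrawn. Each of the 3 groups had 2 samples, A and B, and the deposited peak list of a group was made for both samples together, so 1 list stood for each group and no spread between replicates could be measured. The 2iL list held 91228 intervals over 66.8 Mb, the 48 h list 88810 intervals over 64.5 Mb and the 96 h list 78055 intervals over 55.6 Mb. Median widths were 677, 658 and 645 bp. Median fold enrichments at the summit, which are the authors' values, were 8.29, 8.14 and 8.79. The background recovered from the lists' fold and p values, a measure of the depth behind each list, was 14.2, 15.2 and 13.99 tags per position for 2iL, 48 h and 96 h. Intervals of the 3 lists that overlapped by at least 1 bp were merged into 131410 regions on mm10. Below, a region is lost when it is in the earlier list and absent from the later one, and gained in the reverse case. Intervals in brackets are exact binomial 95% intervals and cover counting error only. Shares at 16 gene lists were placed among 10000 random gene lists matched on regions per gene, and a share outside the middle 95% of these was taken as outside the random range. Of 96 shares, 30 were outside, against 4.8 expected by chance if shares were independent. They are not, since some gene lists share genes, such as Gata4 in both endoderm lists, and the comparisons reuse the same 3 peak lists. Only 5 of the 30 stayed outside under all 6 other settings of list length and gene assignment. These were naive pluripotency lost and neural ectoderm gained between 2iL and 96 h, and formative and primed pluripotency gained at 48 h. The others were 2-cell-like lost at 48 h and at 96 h, both from the same 9 regions in 2iL. The strength and gene distance of the regions were accounted for only between 2iL and 96 h. On that measure naive pluripotency lost was inside the range, at percentile 89.6. Neural ectoderm gained (98.0) and 2-cell-like lost at 96 h (99.4) stayed outside it. Formative and primed pluripotency gained and 2-cell-like lost at 48 h were not put to this check.

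Across the whole time course, most regions close to gene ends stayed listed: 13171 of the 17557 within 1 kb of one were in all 3 lists. The 47176 regions in all 3 lists made up 35.9% (35.6 to 36.2) of the total, and 27.9% (27.5 to 28.3) of them had their summit within 1 kb of either end of a protein-coding gene. Regions found only in 2iL numbered 27369, or 20.8%, and 3.50% (3.29 to 3.73) of these lay within 1 kb of a gene end. The corresponding share was 6.55% (6.15 to 6.98) for the 13748 regions found only at 48 h and 4.63% (4.28 to 4.99) for the 13788 found only at 96 h. Median distances to a gene end were 7.42 kb for regions in all 3 lists, 21.9 kb for 2iL-only regions and 29.98 kb for 96 h-only regions. Regions inside a gene and over 1 kb from a gene end made up 39.0% of those in all 3 lists, 53.3% of 2iL-only, 49.0% of 48 h-only and 50.2% of 96 h-only regions. Another 13153 regions were shared by 2iL and 48 h, and 13614 by 48 h and 96 h. Regions present in 2iL, missing at 48 h and present again at 96 h were the smallest class, with 2562 regions or 1.95%.

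**Figure D1:**
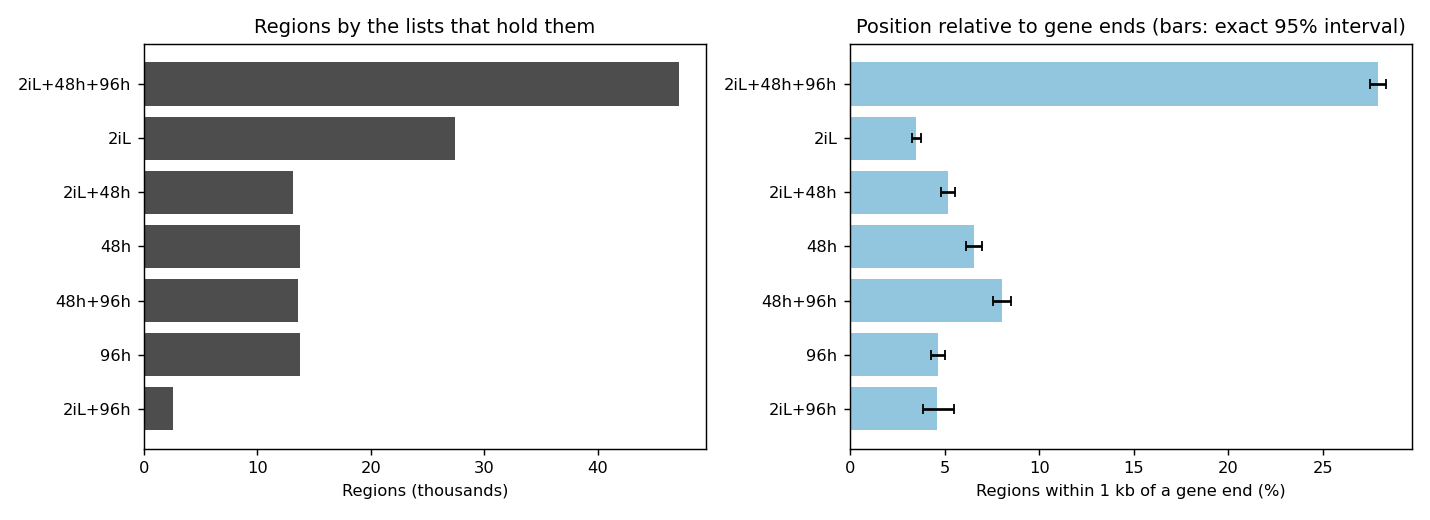
Left, number of regions, in units of 1000, by the lists that hold them, for example 2iL+48h for regions in the 2iL and 48 h lists but not the 96 h list. Right, the share of each class with a summit within 1 kb of a protein-coding gene end (%), with exact binomial 95% intervals as error bars; the class in all 3 lists is at 27.9% and the 2iL-only class at 3.50%.

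The ends of the genes that mark pluripotency and its exit mostly kept a region throughout. Of 31 such genes fixed in advance, 27 had a region within 1 kb of at least 1 end in 2iL, 28 at 48 h and 30 at 96 h, and 26 had one in all 3 lists. All 14 genes of the FGF/ERK target list, among them the feedback inhibitors Spry2 and Dusp6, had such a region in each list. In the naive pluripotency list, 18 of 20 genes had one in 2iL and 16 at 96 h: Dppa3, Tcl1 and Spp1 no longer did, and Esrrb did only later. In the neural ectoderm list, 19 of 22 genes had one in 2iL and all 22 at 96 h, the additions being Pax6, Six3 and Fabp7. Hox genes went from 30 to 34 of 38, with Hoxa2, Hoxa11, Hoxb6 and Hoxd10 added. The housekeeping reference list had such a region at 17 of 20 genes in 2iL, 19 at 48 h and 18 at 96 h, with Actb added. An addition at a gene end was therefore not confined to developmental genes. These members outside the rule for named genes were picked out after their values were seen.

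The first comparison, 2iL against 48 h, asks which accessible regions changed in the first part of the exit from the 2iL state. At 48 h, regions appeared around genes of formative and primed pluripotency, the state that follows naive pluripotency. Of 218 regions at that list's 20 genes in the 48 h list, 95 were gained, or 43.6% (36.9 to 50.4), percentile 99.7. More regions were gained than lost at 13 of the 20 genes and more were lost at 6. Pou3f1 (chromosome 4, 124657646 to 124660655), which encodes the POU factor Oct6, went from 6 to 19 regions, with 13 gained and 0 lost. Fgf5 (chromosome 5, 98254184 to 98277033), a marker of the post-implantation epiblast, went from 2 to 6.

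Of the other members, Otx2, a transcription factor of the epiblast and forebrain, went from 8 to 13 regions with 6 gained and 1 lost. The de novo DNA methyltransferase genes Dnmt3a and Dnmt3b gained 8 and 5 regions and lost 2 each. The epithelial factor Grhl2 gained 13 and lost 5. Lef1, a WNT effector, gained 9 and lost 10. At neural ectoderm genes, 69 of 170 regions at 48 h were gained, 40.6% (33.1 to 48.4), percentile 98.7, and 16 of 22 genes gained more than they lost. This share fell inside the random range when only the stronger part of the list by −log10 p was taken (percentile 94.3), when regions went to the nearest gene body (94.98) and without Map2 (96.015). Formative and primed genes lost 45 of 168 regions, 26.8% (20.3 to 34.2), percentile 2.435, which was inside the range in all 6 alternatives, at 2.685 to 17.155.

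Naive pluripotency genes had few gains at 48 h. At the 20 genes of this list, 39 of 177 regions were gained, 22.0% (16.2 to 28.9), percentile 0.615, and 107 of 245 were lost, 43.7% (37.4 to 50.1), percentile 95.8, which lies within the random range. Losses outnumbered gains at 14 genes and gains outnumbered losses at 1. Klf4 (chromosome 4, 55527137 to 55532475), a reprogramming factor and LIF/STAT3 target, went from 14 to 6 regions, with 8 lost and 0 gained. Tfcp2l1, a partner of the naive network, went from 16 to 6 regions. Tet2, which oxidises methylated cytosine, lost 13 and gained 2 regions, Tbx3 lost 13 and gained 4, Klf5 lost 10 and gained 2, and Prdm14 lost 5 and gained 0. Esrrb, an orphan nuclear receptor, kept 28 regions in number, with 10 lost and 10 gained. At LIF/STAT3 targets, 8 of 58 regions at 48 h were gained, 13.8% (6.15 to 25.4), percentile 0.32. The shortage of gains was within the random range when regions over 20 kb from a gene end were left out, at percentile 4.545 for the naive list and 3.945 for the LIF/STAT3 list. With the stronger part of the list the naive gains were at percentile 15.1.

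The 2-cell-like list, genes of the early embryo that a small share of embryonic stem cells express, lost 8 of its 9 regions by 48 h, or 88.9% (51.8 to 99.7). These counts are small, and 5 of the lost regions lay at a single gene, Zfp352. Zscan4c lost its 1 region and Tcstv3 kept its 1. At Hox genes, 13 of 98 regions were lost, 13.3% (7.26 to 21.6), percentile 0.195, but 14.475 with the stronger part of the list and 3.015 with lists of equal length. Among genes picked only by the number of strong regions that changed, Pkp4, a plakophilin of cell junctions, went from 35 to 13 regions, and the cell-cycle kinase gene Cdk6 from 25 to 12. Phlpp1 went from 21 to 10, Niban1 from 21 to 11, and Arsb from 16 to 5. Mvb12b had the largest gain in this selection, from 19 to 35 regions, and 14 of the 35 were found only at 48 h. The others were Maml3, a Notch coactivator, with 13 gained, Slc38a6 with 12, Lypd6b with 10, and Ctnnbl1 with 13 gained but 10 lost.

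Over all regions, 29931 of 90260 in 2iL were lost at 48 h, 33.2% (32.9 to 33.5), and 27362 of 87691 at 48 h were gained, 31.2% (30.9 to 31.5). Lists moved by random offsets lacked 94.9% of 2iL regions and 94.7% of 48 h regions on average. In the strongest 25% of each list by fold enrichment, 12.5% (12.1 to 12.9) of 2iL regions were lost and 8.34% (7.98 to 8.71) of 48 h regions were gained. The strongest lost region was inside Ahcyl2 (chromosome 6, 29777008 to 29777660, fold 28.9 in 2iL), followed by regions inside Rnf168 (chromosome 16, 32291647 to 32292236, fold 27.6) and Cul1 (chromosome 6, 47494477 to 47495198, fold 26.9). Strong gained regions lay 29.3 kb from Itgb8 (chromosome 12, 119133166 to 119133788, fold 29.0 at 48 h) and inside Rasal2 (chromosome 1, 157180877 to 157181586, fold 28.0), and both were still listed at 96 h.

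The comparison of 48 h with 96 h covers the later part of the time course. Between these times, a small share of regions at neural genes and a larger share at naive genes was lost. At neural ectoderm genes, 32 of 170 regions at 48 h were lost, 18.8% (13.2 to 25.5), percentile 0.03. Zfp521, which drives early neural differentiation, had gone from 13 regions in 2iL to 7 at 48 h, and rose to 16 at 96 h with 11 gained and 2 lost. Pax7 went from 22 to 24 regions, Pax3 from 9 to 12, Pax6 from 13 to 15 and Sox1 from 15 to 14. The list gained 54 of 192 regions, 28.1% (21.9 to 35.1), percentile 95.5, within the range, and percentile 77 without Zfp521. When only the stronger part of the 48 h list by −log10 p was taken, the loss at neural genes was within the random range, at percentile 33.95.

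At naive pluripotency genes, 71 of 177 regions were lost after 48 h, 40.1% (32.8 to 47.7), percentile 97.7. Zfp42, also known as Rex1 and a standard reporter of the naive state (chromosome 8, 43295067 to 43307009), went from 11 to 2 regions, and without this gene the list was at percentile 90.2. Esrrb went from 28 to 16 regions with 13 lost and 1 gained, Klf5 from 11 to 6, Prdm14 from 10 to 6, and Klf2 from 6 to 3. Klf4 and Nanog kept all 6 of their regions each. The naive list fell inside the random range under 3 of 6 other settings, with values from 94.6 to 99.7 over the 6. It gained 16 of 122 regions, 13.1% (7.69 to 20.4), percentile 2.295, inside the range under 5 of 6 settings, at up to 44.1. At general pluripotency genes, 51 of 122 regions were lost, 41.8% (32.9 to 51.1), percentile 97.1, within the range. Sox2 lost 13 and gained 5 of its regions, and Zfp281 lost 11 and gained 0, whereas Pou5f1, which encodes Oct4, kept all 5.

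At formative and primed genes, 72 of 218 regions were lost, 33.0% (26.8 to 39.7), percentile 48.3, and 36 of 182 were gained, 19.8%, percentile 20.5. Pou3f1 lost 6 and gained 0, Fgf5 lost 2 and gained 0, and Grhl2 lost 11 and gained 0. Otx2 lost 2 and gained 2. Germline genes lost 22 of 44 regions (34.6% to 65.4%), percentile 99.7. Prdm1, a regulator of germ cell fate, accounted for 12 of the 22. This call ended under 3 of 6 other settings, where the percentile was as low as 89.6. LIF/STAT3 targets lost 8 of 58 regions, 13.8%, percentile 0.265, and Hox genes 25 of 129, 19.4%, percentile 1.045. Each was inside the range under 1 setting, at 3.315 without regions over 20 kb away and at 3.905 with the stronger part of the list. Markers of extraembryonic endoderm lost 12 of 78 regions, 15.4% (8.21 to 25.3), percentile 0.265, and of trophoblast 19 of 94, 20.2% (12.6 to 29.8), percentile 1.03. These were inside the range under 3 and 2 of 6 settings, and at 95.3 and 44.1 with every gene end within 50 kb. The 2-cell-like list had 2 regions at each time and shared 0 of them. Mesoderm and primitive streak genes gained 36 of 117 regions, 30.8% (22.6 to 39.97), percentile 97.53, of which 8 lay at Kdr, the VEGF receptor gene. This share was inside the range under 4 of 6 settings, at percentile 44.6 with the stronger part of the list by −log10 p. Definitive endoderm genes lost 11 of 61 regions, 18.0% (9.36 to 29.98), percentile 1.48. This was inside the range under 4 of 6 settings, at percentile 53.6 when every gene end within 50 kb was counted. Cxcr4, a chemokine receptor used to sort endoderm, went from 4 to 10 regions.

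Of the genes picked by strong regions, Arl15 went from 30 to 13 regions, Katnal1 from 34 to 18, Mtus2 from 26 to 12, Cradd from 27 to 17, and the chromatin remodeller gene Arid1b from 30 to 21. Gains were seen at Myo16, from 11 to 21 regions, at Cxcr4, at Hs1bp3 from 8 to 12, at the Groucho corepressor gene Tle1 from 3 to 9, and at Tes from 1 to 5. Over all regions, 26901 of 87691 regions were lost, 30.7% (30.4 to 30.98), and 16350 of 77140 were gained, 21.2% (20.9 to 21.5). The recovered background at 48 h was 1.085 times that at 96 h, and an effect of this depth on the losses was not tested. In the strongest 25%, 6.12% (5.80 to 6.44) were lost and 3.87% (3.61 to 4.16) were gained. The strongest lost region lay inside Gm31714 (chromosome 13, 65415011 to 65415366), with a fold of 43.5 in 2iL and 37.2 at 48 h. The next lay 0.046 kb from an end of Serpinb5 (chromosome 1, 106860799 to 106861573, fold 30.4) and 58.1 kb from Ahr (chromosome 12, 35592856 to 35593414, fold 29.5). The strongest gained regions lay inside Pdlim5 (chromosome 3, 142318157 to 142318538, fold 32.3), 20.2 kb from Xrcc4 (chromosome 13, 89828449 to 89829078, fold 29.8) and 58.5 kb from Hs1bp3 (chromosome 12, 8401750 to 8402674, fold 28.1). Those at Pdlim5 and Xrcc4 had also been listed in 2iL.

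**Figure D2:**
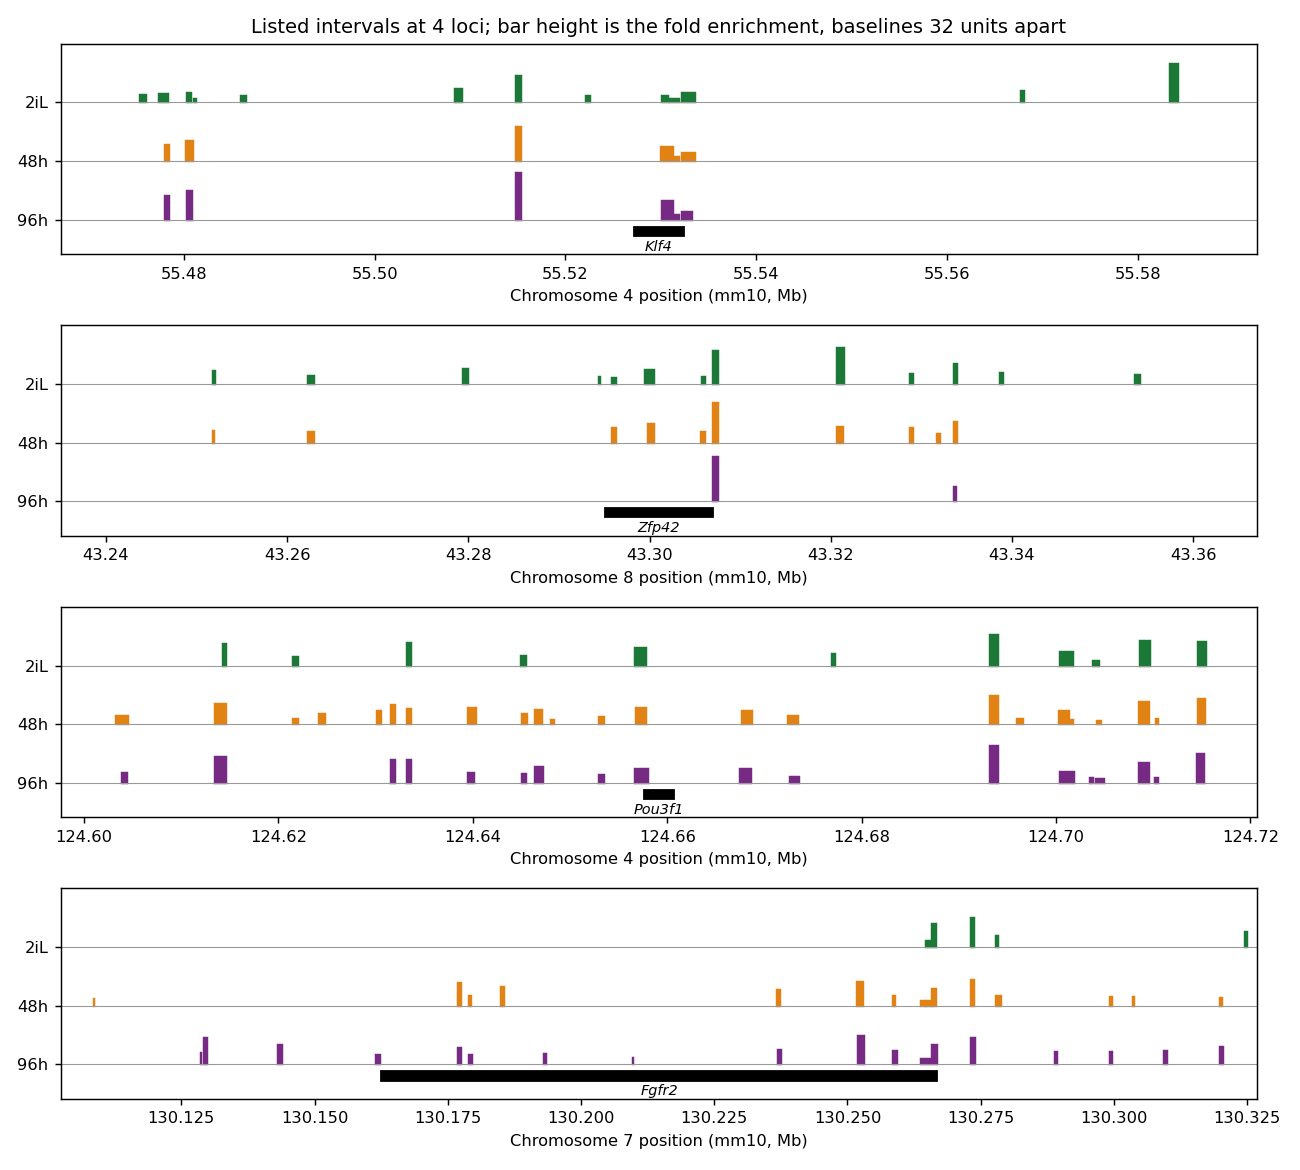
Listed intervals in 2iL (green), 48 h (orange) and 96 h (purple) at Klf4, Zfp42, Pou3f1 and Fgfr2, with 60 kb on either side of each gene; the horizontal axis is the position on mm10 in Mb, the height of a bar is the authors' fold enrichment at the interval's strongest summit, and black bars are genes. Within its assigned regions Zfp42 goes from 14 to 2, Klf4 from 14 to 6, Pou3f1 from 6 to 13 and Fgfr2 from 6 to 23 between 2iL and 96 h.

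The comparison of 2iL with 96 h sets the ends of the time course against each other. Naive pluripotency genes lost regions and gained few. Of 245 regions at the 20 genes, 146 were lost, 59.6% (53.2 to 65.8), percentile 99.2, and of 122 regions at 96 h, 23 were gained, 18.9% (12.3 to 26.9), percentile 0.03. Losses outnumbered gains at 19 of the 20 genes and gains outnumbered losses at 0. Neural ectoderm genes had the opposite balance, with 97 of 192 regions gained, 50.5% (43.2 to 57.8), percentile 99.9, and 46 of 141 lost, 32.6% (24.97 to 41.0), percentile 0.505. The neural losses were inside the range with the stronger part of the list, at 16.4, and with every gene end within 50 kb, at 3.025.

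Among naive genes, Esrrb (chromosome 12, 86361117 to 86521628) lost 20 of 28 regions and gained 8. Tbx3 lost 16 of 28 and gained 3, Tet2 14 of 20 and gained 1, Klf5 13 of 19 and gained 0, Zfp42 12 of 14 and gained 0, and Tfcp2l1 10 of 16 and gained 1. Prdm14, a regulator of the naive and germline states, lost 9 of 15 and gained 0. The region at the upper end of Zfp42 stayed listed, with fold enrichments of 18.7, 22.1 and 24.4 in 2iL, 48 h and 96 h. A region 13.9 kb from that end (chromosome 8, 43320611 to 43321411) had a fold of 20.2 in 2iL and 9.21 at 48 h and was not listed at 96 h. At Klf4, a region 51.3 kb away (chromosome 4, 55583301 to 55584212, fold 21.4) was listed only in 2iL. Nanog lost 3 of 9 regions and Dppa3 lost 4 of 8. These individual regions were chosen after their values were seen. From the strength and gene distance of their regions alone, 135 losses were expected at naive genes against the 146 observed, and on that measure the list was at percentile 89.6, within the random range. The shortage of gains lay within the range when only the stronger part of the 96 h list by −log10 p was taken, with 9 of 57 regions gained (percentile 56.7), and when every gene end within 50 kb was counted (9.665).

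At neural ectoderm genes, 16 of 22 gained more than they lost and 3 lost more than they gained. Pax7 (chromosome 4, 139737059 to 139833530), a paired-box factor of the dorsal neural tube, gained 14 regions and lost 4. Zfp521 gained 12 and lost 9, Pax6, an eye and forebrain regulator, gained 8 and lost 2, and Pax3 gained 7 and lost 5. Sox1, an early neural marker, gained 5 and lost 6. The share gained stayed above the random range in all 6 other settings, at percentiles of 99.4 to 100. It was also at percentile 98.0 after the strength and gene distance of the regions were accounted for. Markers of other cell types were examined in the same comparison. Fibroblast and mesenchymal markers gained 32 of 68 regions, 47.1% (34.8 to 59.6), percentile 97.0, with 12 at Zeb2. Extraembryonic endoderm markers gained 43 of 93, 46.2% (35.8 to 56.9), percentile 95.5, and trophoblast markers 33 of 94, 35.1% (25.5 to 45.6), percentile 36.9. None of these 3 gained shares was outside the random range, and that of the fibroblast list was at percentile 98.6 once strength and gene distance were accounted for. Trophoblast markers lost 33 of 94 regions, percentile 2.47, inside the range under 3 of 6 settings, at 44.96 with the stronger part of the list. Extraembryonic endoderm markers lost 28 of 78, 35.9% (25.3 to 47.6), percentile 11.2, and 1.83 once strength and gene distance were accounted for.

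Formative and primed genes gained 78 of 182 regions, 42.9% (35.6 to 50.4), percentile 85.6, and lost 64 of 168, 38.1% (30.7 to 45.9), percentile 1.925. These losses were at 31.1 with the stronger part of the list and 4.21 with every gene end within 50 kb. They were at 3.11 once strength and gene distance were accounted for. Pou3f1 gained 8 and lost 1, Otx2 gained 6 and lost 1, and Fgf5 gained 2 and lost 0, whereas Lef1 gained 5 and lost 14. Foxp1 gained 9 and lost 10. Of the other germ layer lists, mesoderm and primitive streak genes gained 50 of 117, 42.7% (33.6 to 52.2), percentile 86.8. T, also known as brachyury, gained 2 and lost 2 of 5 regions, Eomes gained 6 and lost 3, and Mixl1 kept its 1 region. Definitive endoderm genes gained 35 of 70 (37.8% to 62.2%), percentile 96.5, within the range, and lost 13 of 48, 27.1% (15.3 to 41.8), percentile 2.47, inside the range under 5 of 6 settings at up to 67.4. Gata4 gained 8 and lost 1, Gata6 gained 6 and lost 1, Foxa2 gained 3 and lost 1, and Sox17 gained 1 and lost 1.

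Of the targets of the pathways that 2iL acts on, LIF/STAT3 targets gained 9 of 57 regions, 15.8% (7.48 to 27.9), percentile 0.2 (3.67 with every gene end within 50 kb), and lost 36 of 84, 42.9% (32.1 to 54.1), percentile 28.4. Socs3, the feedback inhibitor of LIF signalling, had 11, 10 and 11 regions in 2iL, 48 h and 96 h. WNT/beta-catenin targets lost 66 of 141, 46.8% (38.4 to 55.4), percentile 37.0, and gained 42 of 117, 35.9%, percentile 45.15. Axin2, a WNT feedback gene, lost 9 and gained 9 of its regions. FGF/ERK targets lost 70 of 149, 47.0% (38.8 to 55.3), percentile 27.7, with Spred2 losing 17 and gaining 2 and Myc losing 12 and gaining 2. They gained 30 of 109, 27.5% (19.4 to 36.9), percentile 3.105, and percentile 0.9, outside the range, once strength and gene distance were accounted for, with 43.7 expected. General pluripotency genes lost 62 of 116, 53.4% (44.0 to 62.8), percentile 78.3. Pou5f1 had 4, 5 and 5 regions, and Sox2 21, 25 and 17. Germline genes lost 23 of 44, 52.3% (36.7 to 67.5), percentile 86.4. Hox genes lost 18 of 98, 18.4% (11.3 to 27.5), percentile 0.02 (30.3 with the stronger part of the list), and 2-cell-like genes 8 of 9, percentile 99.975. The housekeeping reference list lost 27 of 79, 34.2% (23.9 to 45.7), percentile 8.27, and gained 13 of 65 (11.1% to 31.8%), percentile 2.41, inside the range under 3 of 6 settings at up to 12.8. Once strength and gene distance were accounted for, its gains were at percentile 1.11, outside the range, with 23.2 expected.

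**Figure D3:**
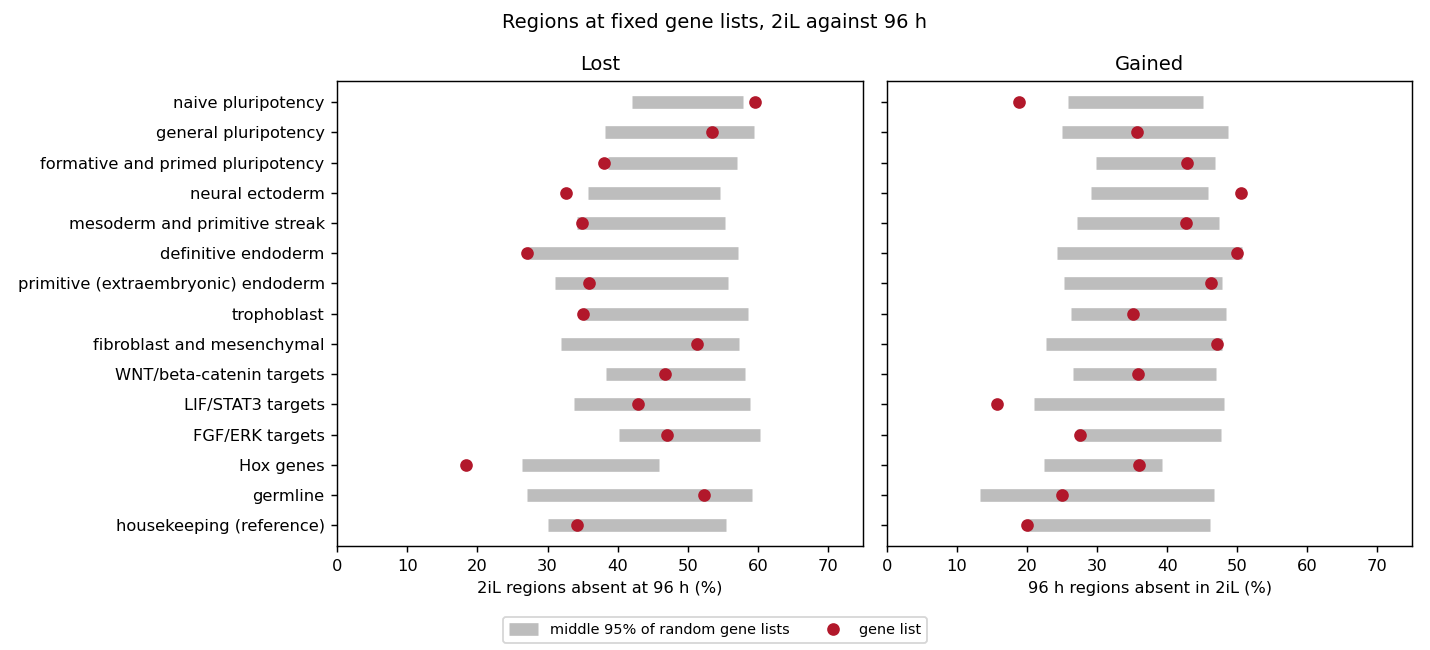
Share of 2iL regions absent at 96 h (left, %) and of 96 h regions absent in 2iL (right, %) at the genes of 15 fixed lists. Red points are the lists and grey bars the middle 95% of 10000 random gene lists matched on regions per gene; naive pluripotency is at 59.6% lost and 18.9% gained, and neural ectoderm at 32.6% lost and 50.5% gained.

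Genes picked by strong regions lost or gained between 2iL and 96 h included no member of the fixed lists. Arid5b (chromosome 10, 68092523 to 68279355) went from 34 to 8 regions, Arl15 from 35 to 13, Etv6, an ETS repressor gene, from 31 to 9, Tcf4 from 25 to 11 and Phlpp1 from 21 to 9. Pkp4 (chromosome 2, 59160850 to 59355205), named in the first comparison, went on to 4 regions, with 31 of 35 lost and 0 gained. Fgfr2 (chromosome 7, 130162451 to 130266808), an FGF receptor gene, went from 6 to 17 to 23 regions in 2iL, 48 h and 96 h, with 20 gained and 3 lost against 2iL. Maml3 gained 14 and lost 4, Kcnma1 gained 11 and lost 1, the ephrin receptor gene Ephb1 gained 11 and lost 1, and the LIM cofactor gene Ldb2 gained 10 and lost 2.

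Over all regions, 40522 of 90260 in 2iL were lost at 96 h, 44.9% (44.6 to 45.2), and 27402 of 77140 at 96 h were gained, 35.5% (35.2 to 35.9). The regions common to 2iL and 96 h made up 42.3% of those in either list, against 51.3% for 2iL and 48 h and 58.4% for 48 h and 96 h. In the strongest 25%, 22.0% (21.5 to 22.6) of 2iL regions were lost and 12.1% (11.7 to 12.6) of 96 h regions were gained. Within 1 kb of a gene end lay 2.51% of those lost and 3.54% of those gained. Of all regions in the strongest 25%, 30.8% in the 2iL list and 36.1% in the 96 h list lay there. Near gene ends as a whole, 1637 of 14926 regions were lost, 10.97%, and 1730 of 15019 were gained, 11.5%. After the region inside Gm31714, the strongest lost regions lay 0.162 kb from an end of Zfp640 (chromosome 13, 66680718 to 66681173), with a fold of 40.8 in 2iL and 20.3 at 48 h, and inside Scmh1 (chromosome 4, 120432428 to 120433201), with 31.8 and 12.9. The strongest gained regions lay 177 kb from Aasdhppt (chromosome 9, 4117106 to 4117866, fold 30.5 at 96 h), 0.855 kb from an end of C030002A05Rik, inside it and Csmd1 (chromosome 8, 17354093 to 17354799, fold 30.4), and 1338 kb from Cdh2, the nearest protein-coding gene (chromosome 18, 18146605 to 18146962, fold 29.5). With all lists shortened to the length of the shortest, the shares lost and gained were 39.95% and 39.8%, since lists of equal length must lose and gain nearly equal numbers.

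**Figure D4:**
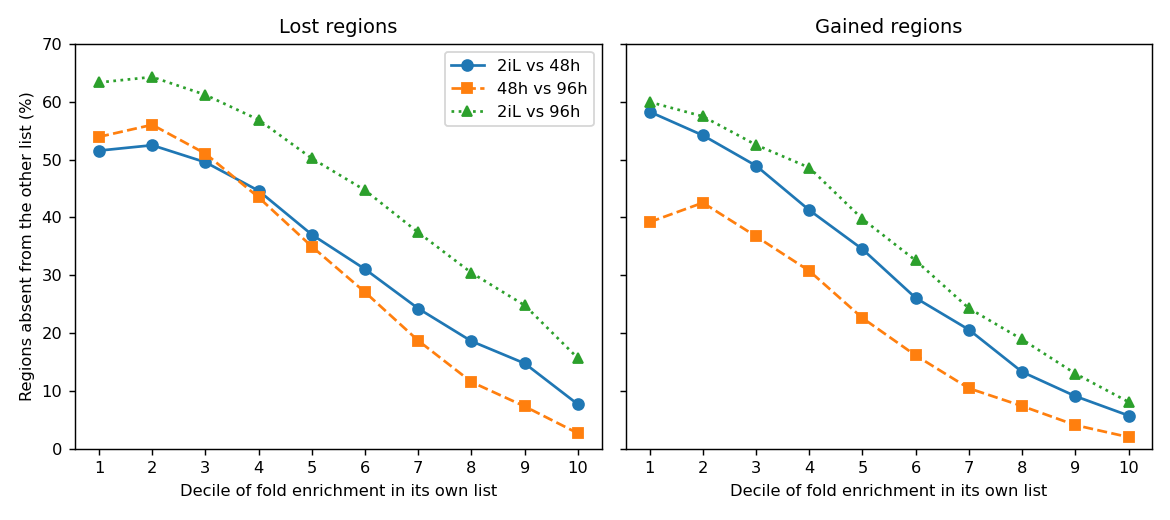
Share of regions absent from the other list (%) by decile of fold enrichment within their own list, from the weakest (1) to the strongest (10), for lost regions (left) and gained regions (right) in the 3 comparisons. Between 2iL and 96 h the lost share falls from 63.4% in the weakest decile to 15.7% in the strongest, and the gained share from 59.97% to 8.10%.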

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

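No paired analysis was possible because each deposited list combines samples A and B, and for the same reason no replicate could be left out. The planned motif alternatives (another window, no GC strata, flanking background, stronger part of the list) were not run. Setting the strongest 25% against another list shortened to the shortest length, and assigning by gene body, were chosen after seeing the data. In the order 2iL to 48 h, 48 h to 96 h and 2iL to 96 h, lost then gained: the upper part of a list by −log10 p against the whole other list gave 16.0% and 10.9%, 8.54% and 4.79%, and 27.0% and 15.1%, fewer since weak regions were left out. Both lists at that upper part gave 30.9% and 28.9%, 26.7% and 16.6%, and 41.5% and 31.6%. Lists of equal length gave 30.9% and 30.8%, 24.95% and 24.9%, and 39.95% and 39.8%, where near equality follows from the construction. Summits within 250 bp gave 31.6% gained at 48 h, and 45.3% lost and 36.0% gained at 96 h against 2iL. Requiring 50% of the shorter interval, or autosomes only, left all 6 shares within their intervals.

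Of strong regions, the strongest 10% gave 7.69% and 5.75%, 2.68% and 2.02%, and 15.7% and 8.10%. Strength by −log10 p gave 7.92% and 3.81%, 1.68% and 1.03%, and 15.7% and 5.53%. Shortening the other list gave 13.8% and 9.90% for 2iL to 48 h, 4.56% gained after 48 h and 13.7% gained between 2iL and 96 h. More was lost than gained in each of these settings. Classes at equal length were 37.3% in all 3 lists, 18.2% 2iL only, 8.35% 48 h only and 14.2% 96 h only, and by summits 30.8%, 22.3%, 11.98% and 11.8%. Shares near a gene end within 500 bp were 23.5% in all lists, 1.82% 2iL only and 2.52% 96 h only. With 2 kb outside and 500 bp inside of the end they were 4.79% 2iL only and 5.71% 96 h only.

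For the gene lists, 574 alternative percentiles were computed: 478 kept their side of the limits, 59 fell inside, 31 passed a limit and 6 changed direction. Of the 30 shares outside the random range, 5 kept it under all 6 settings: naive lost and neural ectoderm gained between 2iL and 96 h, formative gained at 48 h, and 2-cell-like lost at 48 h and 96 h. Accounting for strength and gene distance between 2iL and 96 h, which is not among the 6, moved 7 shares across a limit. Naive lost (89.6) and formative lost (3.11) came inside the range. Mesoderm lost (1.79), extraembryonic endoderm lost (1.83), fibroblast gained (98.6) and FGF/ERK gained (0.9) went outside it, as did Hox gained, from 89.2 to 1.97. Naive gained at 96 h moved to percentile 9.665 with every gene end within 50 kb and to 56.7 with the stronger part of the list. The former setting also turned definitive endoderm lost after 48 h (53.6) and between 2iL and 96 h (67.4), and extraembryonic endoderm lost after 48 h (95.3). The latter turned extraembryonic endoderm lost after 48 h (53.4) and mesoderm gained after 48 h (44.6). The cause was not tested for these. Depth was not varied, so what it limits was not tested. Weak regions were absent more often: 63.4% of the weakest decile of 2iL regions was absent at 96 h, against 15.7% of the strongest.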

Other observations

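Gene families also differed, and some of them hold members of the fixed lists, such as Klf2, Klf4 and Klf5, Sox2, Wnt3, Col4a2, Zfp42 and Zfp521, so they are not independent of those lists. Families were taken as genes sharing a symbol stem, with at least 15 members, and compared after strength and gene distance were accounted for, a scan chosen after seeing the data. Between 2iL and 96 h, Wnt ligand genes lost 27 of 109 regions, 24.8%, where 49.7 were expected (percentile 0), and Sox genes lost 43 of 125, 34.4%, where 59.1 were expected (0.88). Collagen and other Col genes lost 36.0% (percentile 0.11) and gained 129 of 275, 46.9% (99.85). Trim genes lost 28.3% (0.02). Regions at vomeronasal (Vmn) and olfactory (Olfr) receptor genes were lost in 61.7% and 53.8% (both percentile 100), and those at Olfr genes were also gained in 41.2% (100). Klf genes gained 28 of 115 regions where 40.2 were expected (1.91), and zinc finger genes named Zfp gained 25.4% (0.47). In all, 15 of 119 families for losses and 14 of 116 for gains were outside the random range, against 5.95 and 5.8 expected by chance. Random genes came from the whole genome, and neighbouring regions tended to share their fate. Where members of a family lie side by side, the random range may therefore be too narrow and these percentiles too extreme.

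Strong regions at some gene ends changed. Regions within 1 kb of an end of Zfp640, Ang2, Zfp977 and Klf17, listed in 2iL with folds of 40.8, 23.7, 22.1 and 18.4, were absent at 96 h. Those at Gpr165, Rgs4, Fez1, Camk1g and Cdh12 were absent in 2iL and had folds of 24.5, 21.6, 20.5, 19.97 and 18.6 at 96 h. After Mvb12b, the loci with the most regions listed only at 48 h were Med13l with 12, Pitpnc1 with 11, and Dnah8, Cachd1, Casz1, Katnal1 and Sall1 with 10 each. Among chromosomes 1 to 19 and X, the share of 2iL regions lost at 96 h ran from 39.9% on chromosome 19 to 49.8% on chromosome 18. On chromosome Y, 3 of 17 regions were lost, 17.6% (3.80 to 43.4). These genes were chosen after their values were seen.

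Of the 7 tests below, those of depth and of the list limit were chosen after the result was seen. More regions were lost than gained between 2iL and 96 h. A deeper 2iL pool is argued against by a background ratio of 1.015. This ratio covers 2iL against 96 h only. The background at 48 h was 1.07 times that in 2iL and 1.085 times that at 96 h. Whether depth added to the gains at 48 h or to the losses after it was not tested. The 5th percentile of −log10 p of the 96 h list was −6.01 relative to that of 2iL, so the 96 h list was not the stricter one by p. The lowest score was 540 in each of the 3 lists, so p need not have set their limits. This value therefore cannot exclude a stricter selection of the 96 h list on another measure. Among the 15000 strongest regions of each list, with lists cut to equal length, 18.8% (18.2 to 19.4) were lost and 11.6% (11.1 to 12.1) gained. The ratio was 1.62, so more was lost than gained among strong regions as well. Over all regions, lists of equal length must lose and gain nearly equal numbers. For that reason this test cannot tell whether regions at the edge of the threshold caused the larger total loss. No biological explanation was tested. Differences between samples A and B, or in the quality of the libraries, stay open because the lists combine them.

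Naive pluripotency genes lost a larger share of regions than other genes. A single locus as the source is argued against by percentile 98.1 without Esrrb, the gene with the most losses. Weak or gene-distant regions at these genes could account for the excess: given fold decile and distance class, 135 losses were expected and 146 observed, at percentile 89.6. The shortage of gains stayed outside the range when strength and distance were accounted for, with 23 gains against 46.1 expected (percentile 0). It was inside the range with the stronger part of the list (56.7) and with every gene end within 50 kb (9.665). Such a shortage was not particular to naive genes. On the same measure the housekeeping reference list gained 13 against 23.2 expected (percentile 1.11) and LIF/STAT3 targets 9 against 19.5 (0.19). FGF/ERK targets (0.9) and Hox genes (1.97) were also below the range, and neural ectoderm (98.0) and fibroblast (98.6) lists above it.

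Neighbouring regions tended to share their fate. Among 90239 pairs of adjacent 2iL regions, 20072 were lost together at 96 h. Shuffling within chromosome, fold decile and distance class gave a ratio of observed to shuffled pairs of 1.06, and shuffling within 5 Mb windows gave 1.07. Each observed number was above the highest of 200 shuffles (19190 and 18998). The first shuffle argues against weak regions lying together as the whole cause. The second was matched on coarser classes of fold and distance. It therefore cannot separate a change of copy number over large segments from weak regions lying together. Where the gap was under 2 kb, 56.2% of regions were lost if the region before was lost and 39.5% if it was kept, against 47.7% and 41.2% for gaps of 10 to 50 kb and 49.1% and 43.1% for larger gaps, without matching on strength. Intervals split from a single broad site could add to the pattern at short gaps, which was not tested, but a gap over 10 kb exceeds the longest interval, of 3415 bp.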
